A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

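Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done in budding yeast of the laboratory strain BY4741 with an antibody against histone H3 phosphorylated at threonine 45 (H3T45p) and an antibody against the C terminus of H3, which recovers H3 whatever its modification. Cells were grown in rich medium to mid-log phase and were either left untreated or treated with 200 mM hydroxyurea for 2 h, per the labels' protocols. Chromatin was crosslinked and sheared by sonication, per the labels' protocols. There were 4 libraries, 1 for each antibody and treatment, so no group had a replicate. The sample titles number both hydroxyurea libraries 1 and both untreated libraries 2. If those numbers mark a batch, batch and treatment cannot be told apart. The groups share fewer than 2 numbers, so no pairing was used. The 4 libraries analysed include no input or mock immunoprecipitation, so DNA that any antibody would recover was not measured.

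The authors deposited for each library a signal in windows of 150 bp. Within each library every value was a whole multiple of the smallest value above 0, to within 0.001 of a read, for 100% of values, so whole reads per window were recovered. The deposited signal is therefore a read count per window, divided by the authors by one factor per library. BWA 0.5.9-r16 and DESeq are named in the submitters' processing notes, without a role or order. The genome build and the rule of the peak call are not given in the sources used here. For each H3T45p library the authors also deposited a peak list, which gives positions without a score. A further pair of tracks from the authors holds the difference between the H3T45p and the H3 signal, one per treatment, for nuclear chromosomes. Each difference was recovered from the deposited signals with factors between 0.9998 and 1.0003.

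The recovered reads in windows were 23588153 for H3T45p and 28690293 for H3 in hydroxyurea, and 25105783 for H3T45p and 27319637 for H3 in untreated cells. The libraries hold 81046 windows, of which 80474 are nuclear and 572 mitochondrial. One factor per library brings libraries to a common scale, so a change in the total amount of H3T45p per cell is not measured by these values, and all changes are relative within the genome.

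Since the build of the files is not named, windows were not assigned to genes, and regions are given by chromosome number and by position in the files' own coordinates, counted from 1. The plan fixed before the data were examined allowed for this with blocks of 10 consecutive windows (1.5 kb) in place of genes. Windows were kept where the H3 signal was at least 25% of the genome median of its library in both conditions (69.3 in hydroxyurea and 69.9 in untreated). This left 70662 nuclear windows (87.8%). Blocks needed 3 or more kept windows, which gave 7697 blocks. For each block the log2 ratio of H3T45p over H3 was taken from the mean signals, with 28.3 (10% of the genome median over the 4 libraries) added to both. The change with hydroxyurea is the ratio in hydroxyurea minus the ratio in untreated cells. The changes of H3 and of H3T45p alone, hydroxyurea over untreated, were computed in the same way.

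With 1 library per group no residual degrees of freedom remain, so neither a count model nor any other test of the conditions was run, and no p-value is given. Blocks were called by a fixed rule of size, 0.5 or more on the log2 scale in either direction. The error given for a block is the jackknife standard error over its windows, which measures spread within the libraries. Odd and even windows of the same blocks were set against each other as a check within the libraries. Intervals for shares and ratios of reads are exact binomial (Clopper-Pearson) at 95%. The mitochondrial ratio between conditions instead has a normal interval on the log scale. Reads are not independent molecules, so these intervals cover counting error only. Intervals of the background tests are from 1000 bootstrap draws of peaks. The interval of the slope of the H3T45p change is based on the jackknife SE over chromosomes. Overlaps of peaks were set against 10000 circular shifts along each chromosome, and medians of block lists against 10000 random lists matched on H3 signal in 10 classes, both as descriptions of these libraries.

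The named regions follow a rule fixed before the data were examined, with blocks in place of genes. They are the 10 blocks with the highest and the 5 with the lowest ratio in each condition, the 10 highest and 5 lowest changes, and the 5 widest peaks of each list with ties kept, since no score was given. Parts of the plan that need gene positions were not run. These are the gene lists, the named genes, the share of peaks in genes, tRNA genes, repeats and origins, the change of H3 at early and late origins, the 5' and 3' parts of genes, and the 500 bp upstream of genes. The following were chosen only after the data had been seen: the classes by H3 level, the distance to chromosome ends by block, the windows called by one ratio rule, the lists by position, and the domains of raised H3. The alternatives tried were other pseudocounts, H3 filters, scalings, averaging and size rules, and other settings for peaks and domains.

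The block computation was tested on simulated reads before use. For the change with hydroxyurea over 7697 blocks, planted changes of -1, -0.5, 0.5 and 1 in 50 blocks each came back with medians of -0.90, -0.45, 0.46 and 0.94, and all of them lay at or past 0.5 of the planted size. Of 7497 unchanged blocks, 0 passed the rule, and their SD was 0.050. The simulation holds counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.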

Results

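H3T45p and total H3 were mapped along the genome of budding yeast with and without hydroxyurea, a drug that inhibits ribonucleotide reductase, depletes deoxynucleotides and stalls replication forks. Threonine 45 of H3 lies near the point where DNA enters and leaves the nucleosome, and the series concerns its phosphorylation by the replication kinase Cdc7. Each of the 4 groups held 1 library, with 23588153 to 28690293 reads in windows, so no difference between the conditions has a replicate check. The signal of 1 nuclear window of 150 bp had a median of 283 for H3T45p and 277 for H3 in hydroxyurea, and of 289 and 280 in untreated cells. In all libraries 3023 nuclear windows (3.76%) were at 0. Across kept windows of the genome, which are not independent, the signals of H3T45p and H3 followed each other with a Spearman correlation of 0.956 in untreated cells and 0.944 in hydroxyurea. The correlation of H3 between the conditions was 0.920.

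The first comparison asked where H3T45p departed from H3 in untreated cells. Blocks that passed the size rule on the higher side were few and lay mostly near chromosome ends. Most of those that passed it on the lower side were among the blocks with the most H3. Of 7697 blocks of 1.5 kb, 13 had a log2 ratio of H3T45p over H3 of 0.5 or more and 199 of -0.5 or less, about a median of -0.08. Of the 13, 10 lay within 20 kb of an end, and of the 199, 177 were in the highest of 10 classes of H3 signal. Without the filter on low H3, 27 blocks were higher and 190 lower. The highest ratios were 2.13 ± 0.82 (jackknife SE within the library, as for all blocks) at chromosome 4 from 1 to 450 and 1.73 ± 0.94 at chromosome 11 from 666001 to 666450, both at the chromosome's end. The block at chromosome 3 from 1 to 1500 had 1.05 ± 0.55. At such terminal blocks 1 or a few windows carry the ratio, as their errors show. The other blocks at an end among the 10 highest were at chromosome 9 from 439501 (0.66 ± 0.86) and chromosome 11 from 1 (0.66 ± 0.65; -0.0061 from its odd windows alone). The block at chromosome 8 from 556501, 5.7 kb from the end, had 0.81 ± 0.84.

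The other 4 of the 10 highest lay near the right end of chromosome 3. They were 0.72 ± 0.04 from 295651 to 296700, 0.69 ± 0.14 from 291001 to 292500, 0.65 ± 0.04 from 306001 to 307350 and 0.65 ± 0.12 from 294001 to 295500. With a pseudocount of 50% of the genome median these were 0.47, 0.40, 0.42 and 0.41, all under the size rule. The lowest ratios were -0.97 ± 0.11 at chromosome 1 from 25501 to 25950, where the untreated H3 signal was only 208, -0.90 ± 0.24 at chromosome 12 from 252001 to 253350, -0.89 ± 0.04 at chromosome 2 from 1501 to 2250, -0.88 ± 0.23 at chromosome 13 from 408001 to 409500 and -0.88 ± 0.12 at chromosome 3 from 105001 to 106500. The split of the calls depended on the scale. With values centred on their median it was 23 higher and 92 lower, and with the median of each class of H3 signal subtracted it was 14 and 15, with 19 of the 212 original calls retained. Under that subtraction the lowest blocks on chromosomes 2, 13 and 3 were at -0.49, -0.48 and -0.48, short of the size rule. Those on chromosomes 12 and 1 were at -0.50 and -1.11.

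In hydroxyurea the departures were almost all upward. The ratio was 0.5 or more in 110 blocks and -0.5 or less in 1, the block at chromosome 12 from 373651 to 375000 (-0.59 ± 0.08), about a median of 0.01. Of the 110, 87 held a window of the hydroxyurea peaks called by the authors, as did 333 of all 7697 blocks. Those peak windows have high ratios in the same libraries, so this overlap is favoured by construction. Of the 110, 17 lay within 20 kb of an end. Of the 10 highest blocks 6 were at a chromosome end, with 3.57 ± 1.02 at chromosome 4 from 1, 3.17 ± 1.08 at chromosome 11 from 666001, 2.18 ± 0.72 at chromosome 3 from 1, 2.01 ± 1.14 at chromosome 9 from 439501, 1.60 ± 0.69 at chromosome 10 from 744151 and 1.59 ± 1.19 at chromosome 11 from 1 (0.32 from its odd and 2.05 from its even windows). The blocks at chromosome 8 from 556501 and chromosome 12 from 11251, within 20 kb of an end, had 1.75 ± 1.08 and 1.72 ± 0.94. With an H3 filter at 50% of the median the chromosome 12 block was at 0.76. The chromosome 10 block was at 0.89 from the mean of the log2 ratios of its windows. The 2 inner blocks among the 10 highest were chromosome 11 from 517501 to 518550 (1.48 ± 0.23) and chromosome 15 from 978001 to 979500 (1.40 ± 0.33). The other 4 lowest ratios ranged from -0.48 to -0.46, at chromosome 4 from 520051, chromosome 5 from 249001, chromosome 6 from 751 and chromosome 8 from 1501. The count of 111 called blocks was 193 without the filter on low H3 and 64 with a filter at 50% of the median. Without the filter all 193 were higher, the chromosome 12 block from 373651 was at -0.23 and the chromosome 4 block from 520051 at -0.04. With a pseudocount of 50% of the median, 51 blocks were higher and 0 lower.

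The next comparison set the ratio in hydroxyurea against that in untreated cells. The ratio was higher by 0.5 or more in 431 blocks and lower by as much in 28, and the median block was higher by 0.10. Among the 431 blocks, H3T45p was higher in 390 and H3 was lower in 387, and both held in 346. Their median change was 0.35 for H3T45p and -0.31 for H3. The change of the ratio equals the change of H3T45p minus that of H3. Choosing blocks by it favours higher H3T45p and lower H3 by construction, so these counts are no separate result. A window of the hydroxyurea peaks lay in 169 of the 431 blocks, against 333 of all 7697 blocks, which the call in hydroxyurea also favours. Of the 431, 136 were among the blocks at or below -0.5 in untreated cells. The highest changes were 1.72 ± 0.22 at chromosome 11 from 517501, 1.63 ± 0.25 at chromosome 15 from 978001, 1.51 ± 0.43 at chromosome 7 from 856501, 1.44 ± 0.15 at chromosome 11 from 666001 and 1.43 ± 0.20 at chromosome 4 from 1. They were followed by 1.40 ± 0.29 at chromosome 13 from 352501, 1.35 ± 0.28 at chromosome 9 from 439501, 1.34 ± 0.27 at chromosome 7 from 271501, 1.30 ± 0.31 at chromosome 15 from 987001 and 1.24 ± 0.54 at chromosome 7 from 609001. In each of these 10 blocks H3T45p was higher and H3 lower in hydroxyurea, which the choice by the change of the ratio favours. At chromosome 11 from 517501 the H3 signal was 150 in hydroxyurea and 347 in untreated cells, and the H3T45p signal was 468 and 290. The change at chromosome 4 from 1 was 0.85 from the mean of the log2 ratios of its windows and 1.13 without the H3 filter. The lowest changes were -0.84 ± 0.05 at chromosome 14 from 177151 to 178500, -0.80 ± 0.05 and -0.78 ± 0.15 at the chromosome 3 blocks from 295651 and 291001, -0.68 ± 0.07 at chromosome 8 from 22501 and -0.67 ± 0.14 at chromosome 3 from 306001.

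Centring the changes on their median, a shift of -0.10, left 225 blocks higher and 77 lower, so that 74.5% of the calls were higher in place of 93.9%. Subtracting the median of each class of H3 signal left 158 higher and 4 lower, of which 138 were among the original calls. The number of lower calls depended on the setting, with 216 higher and 1 lower at a pseudocount of 50% of the median, and 406 and 5 at an H3 filter of 50%. The change from odd windows and that from even windows of the same block had a Pearson correlation of 0.820 over 7485 blocks, which are not independent. This shows repeatability within the libraries and not between cultures.

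The ratio was then set against the H3 signal of the block, in 10 classes of about 770 blocks. In untreated cells the median ratio fell from 0.14 in the class with the least H3 to -0.39 in the class with the most. In hydroxyurea it stayed between -0.04 and 0.03. The change with hydroxyurea therefore ran from -0.18 in the class with the least H3 to 0.42 in the class with the most, which held 225 of the 431 blocks with a higher ratio. Of the 28 blocks with a lower ratio, 27 were in the class with the least H3. The untreated H3T45p library had a narrower range of signal, with nuclear quartiles of 178 and 409. They were 156 and 447 for untreated H3, and 158 and 452 for H3T45p and 155 and 436 for H3 in hydroxyurea. The trend of the change with the H3 level thus rests on that 1 library without a replicate.

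**Figure D1:**
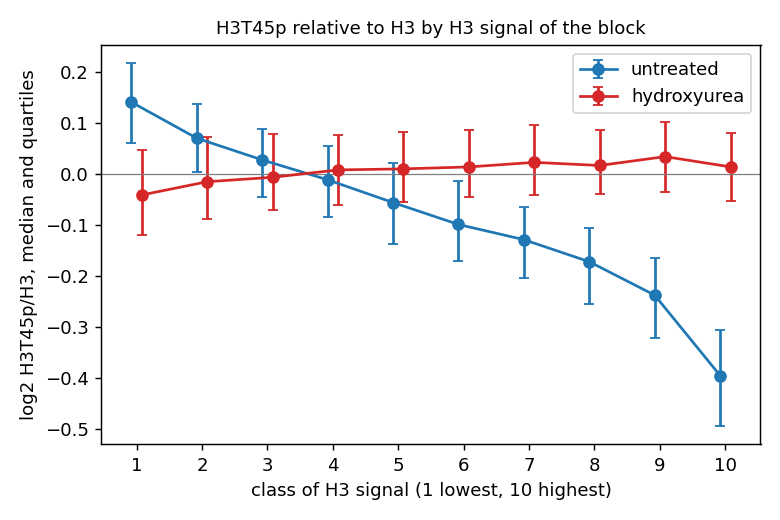
Points show the median log2 ratio of H3T45p over H3 and bars the quartiles over blocks (vertical axis) in 10 classes of H3 signal from lowest to highest (horizontal axis), for untreated cells and hydroxyurea, 1 library each. The untreated medians go from 0.14 to -0.39, and the hydroxyurea medians stay between -0.04 and 0.03.

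The regions called by the authors were more numerous in hydroxyurea, with 630 peaks over 180 kb against 87 peaks over 19.2 kb in untreated cells. The median width was 300 bp in hydroxyurea and 150 bp in untreated cells. All 87 untreated peaks were overlapped by a hydroxyurea peak, where shifted peaks gave a mean of 1.64 and at most 11. Away from the chromosome ends by over 20 kb the overlap was 59 of 59. The shifts do not match the H3 level. Of the windows of untreated and hydroxyurea peaks, 95.3% and 85.25% lay under the genome median of untreated H3. Shifted peaks therefore understate the overlap of 2 lists that both favour regions poor in H3. Conversely, 13.8% of the hydroxyurea peaks (11.2 to 16.8%) overlapped an untreated peak. Under a single rule, a signal of H3T45p at least 2 times that of H3 with 50 or more reads in the pair, 803 windows passed in untreated cells (1.05%) and 2231 in hydroxyurea (2.93%). The opposite rule, H3 at least 2 times H3T45p, was met by 221 and 494 windows. With 200 or more reads the first rule was met by 229 and 1399 windows and the opposite rule by 209 and 44, so the order of the opposite counts turned with the read minimum. With a ratio of 3 the passing windows were 244 and 1183. The lists differ in length and the rule of the call is not given in the sources used here, so the difference in the number of peaks is the authors' result and no measure of H3T45p by itself.

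The called regions were poor in H3. Among windows with H3 above 0, the lowest ratio of H3T45p over H3 in the hydroxyurea peaks was 2.02 in hydroxyurea. In the untreated peaks it was 2.72 in untreated cells. Windows with such ratios favour a low H3 signal in the libraries of the call. For the hydroxyurea list they also favour higher H3T45p and lower H3 in hydroxyurea than in untreated cells. In the windows of the hydroxyurea peaks the median H3 signal was 59.8 in hydroxyurea and 88.6 in untreated cells, and the median H3T45p signal was 306 and 152. In the windows of the untreated peaks the H3 medians were 39.4 and 50.7, and the H3T45p medians 489 and 223, again for hydroxyurea and untreated cells. H3T45p was higher in hydroxyurea in 96.1% of the windows of the hydroxyurea peaks and in 99.2% of those of the untreated peaks. H3 was lower in 86.6% and 74.2%. Of the peak windows, 58.4% in hydroxyurea and 81.2% in untreated cells fell under the H3 filter, so the block values leave out most of them.

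**Figure D2:**
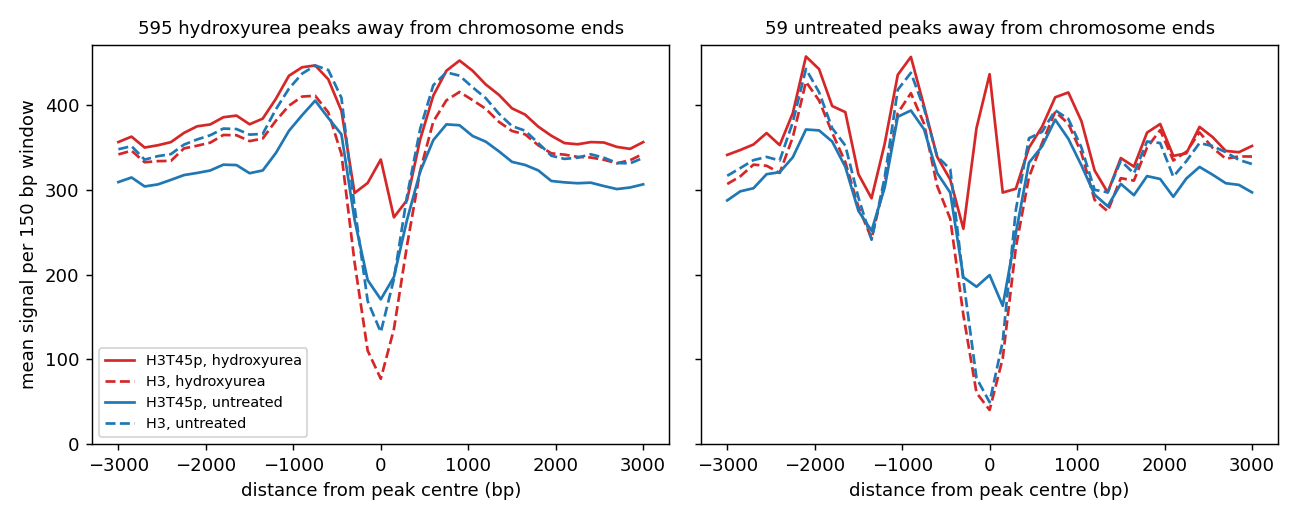
Lines show the mean signal per window of 150 bp (vertical axis) against the distance from the peak centre in bp (horizontal axis) in the 4 libraries, at 595 hydroxyurea peaks (left) and 59 untreated peaks (right) over 20 kb from chromosome ends. At the centre of the hydroxyurea peaks H3 is at 77.2 and H3T45p at 336 in hydroxyurea, against 132 and 171 in untreated cells. At the untreated peaks these means are 40.4, 437, 49.6 and 200. At 750 bp on either side of the hydroxyurea peaks, H3T45p in hydroxyurea is at 447 and 441, above its level at the centre. At the untreated peaks it is at 399 and 409 there, below the centre.

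The widest hydroxyurea peaks lay inside chromosomes. At chromosome 15 from 987301 to 988800 the ratio of H3T45p over H3 was 4.39 in hydroxyurea and 0.95 in untreated cells, and at chromosome 12 from 232201 to 233550 it was 2.90 and 1.09. The other 7, all 900 bp wide, had ratios of 3.78 at chromosome 11 from 354901, 8.65 at chromosome 12 from 370201, 6.67 at chromosome 15 from 109201, 5.16 at chromosome 15 from 978451, 5.76 at chromosome 16 from 214351, 6.09 at chromosome 16 from 502351 and 4.35 at chromosome 5 from 140551. Their ratios in untreated cells were 1.19, 2.995, 1.44, 1.08, 2.08, 0.86 and 1.13 in the same order. The 5 widest untreated peaks, of 450 bp, had ratios of 7.98 at chromosome 3 from 1, 5.60 at chromosome 6 from 4501, 4.75 at chromosome 10 from 75451, 3.87 at chromosome 12 from 370501 and 3.17 at chromosome 5 from 442051. In hydroxyurea these were 21.9, 14.2, 12.3, 13.1 and 9.32. The hydroxyurea peaks were chosen by the call in hydroxyurea, which favours a higher ratio there.

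Peaks of both lists lay within 10 kb of chromosome ends more often than shifted peaks, and those of the untreated list also within 20 kb. A hydroxyurea peak touched 22 of the 32 ends in the files and an untreated peak 19. Within 20 kb of an end lay 28 of the 87 untreated peaks (32.2%, 22.6 to 43.1%), where shifts gave a mean of 5.07 and at most 16. The hydroxyurea list had 35 of 630 there (5.56%, 3.90 to 7.64%), against a mean of 33.0 in shifts, 39.4% of which gave as many. Within 10 kb lay 26 untreated peaks, where shifts gave a mean of 2.54 and at most 12, and 30 hydroxyurea peaks, where they gave a mean of 16.6 and 0.22% of them gave as many. In the last 3 kb the log2 ratio over all kept windows was 0.26 in untreated cells and 0.77 in hydroxyurea, and it was higher in hydroxyurea at 16 of the 18 ends with kept windows there. From 3 to 10 kb it was 0.02 and 0.07. Beyond 40 kb it was -0.14 in untreated cells and 0.03 in hydroxyurea, and higher in hydroxyurea for 32 of 32 ends. The count of 16 of 18 therefore does not set the ends apart. The median change over ends was 0.37 in the last 3 kb, 0.06 from 3 to 10 kb and 0.19 beyond 40 kb. The median ratio over the 318 blocks within 20 kb was 0.04 in untreated cells, at percentile 100 of random lists matched on H3. It was -0.02 in hydroxyurea, at percentile 4.58. The median change of these blocks was -0.02, at percentile 0.04, where random lists gave 0.02. The random lists hold scattered blocks, while blocks near an end are neighbours and neighbours resemble each other, so such percentiles come out too extreme.

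H3 itself changed over long stretches. It was 0.5 or more higher in hydroxyurea in 79 blocks and lower by as much in 235, and the median block was at -0.05. A running mean over neighbouring blocks, with a threshold of 0.15 over the median chosen after the profiles of chromosomes 3 and 6 had been seen, gave 37 domains of raised H3 on all 16 chromosomes. They covered 2662.8 kb (22.1% of the genome), with a median length of 63 kb. The longest were chromosome 3 from 1 to 139500, chromosome 15 from 232501 to 364500, chromosome 5 from 58501 to 189000 and chromosome 12 from 63001 to 189000. By construction H3 was higher inside than outside, by 0.35 in the median. H3T45p was also higher, by 0.40 (1.32-fold), and in all 37 domains its median change lay above the median outside. The change of the ratio of H3T45p over H3 had a median of 0.14 inside and 0.09 outside. Random lists of scattered blocks matched on H3 had a median of 0.16 (central 95% 0.155 to 0.172), so the order turned with the reference. The H3 change by which the domains were chosen enters these comparisons, so no direction is read from them. Blocks whose ratio was higher by 0.5 or more made up 6.17% of the blocks inside and 5.44% of those outside. With a threshold of 0.25 the domains covered 1348.5 kb.

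**Figure D3:**
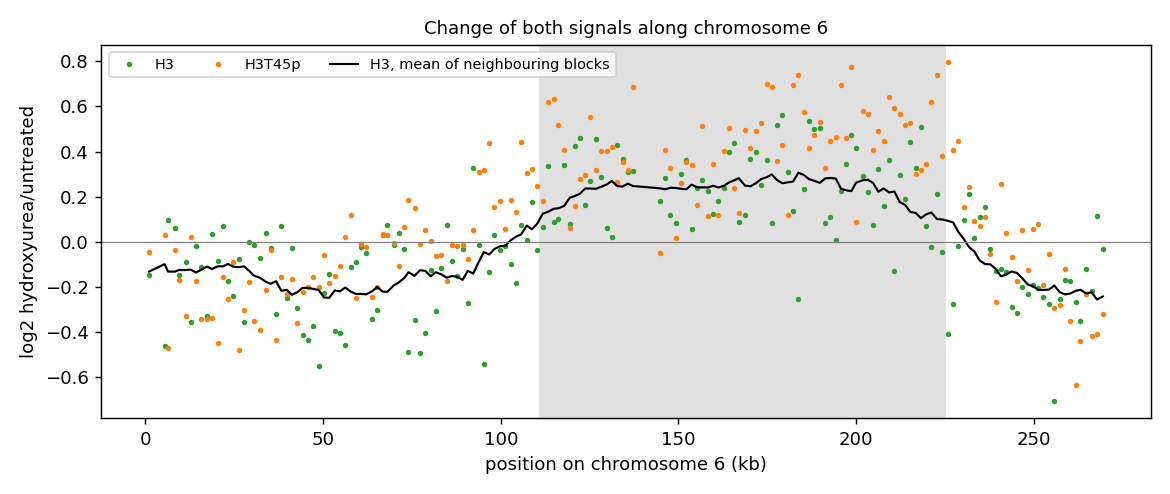
Points show the log2 signal in hydroxyurea over that in untreated cells (vertical axis) for H3 and H3T45p in each block along chromosome 6 (horizontal axis, kb), the line the mean H3 change of the neighbouring blocks, and the shaded stretch the domain from 111151 to 225000. Inside the domain the median change is 0.26 for H3 and 0.41 for H3T45p.

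The authors' deposited difference of H3T45p minus H3 was above 0 in 50.6% of the windows that are not 0 in hydroxyurea (50.3 to 51.0%) and in 50.2% in untreated cells (49.8 to 50.6%). Its mean was 10.4 in hydroxyurea and -30.0 in untreated cells. With each track divided by its genome median the shares were 45.5% and 44.6%.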

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

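All of the following were found after the data had been seen, and none was tested between conditions, since each group held 1 library. Mitochondrial windows, which enter no comparison above, held more H3T45p reads than H3 reads. Of every 1000000 reads in windows, they held 519 (509.8 to 528.3) in the H3T45p library of hydroxyurea cells and 48.7 (46.2 to 51.4) in the H3 library, and in untreated cells 316 (309 to 323) and 33.7 (31.5 to 35.9). The share in the H3T45p library was 10.7 times that in the H3 library in hydroxyurea and 9.39 times in untreated cells. Mitochondrial DNA is not packed in nucleosomes, so these reads do not measure H3T45p.

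Some blocks departed from 0 in the library pair of one condition and lay on the other side of 0 in that of the other. The difference was not tested. The ratio of H3T45p over H3 was 0.5 or more in untreated cells and under 0 in hydroxyurea in 3 blocks, all on chromosome 3, from 291001, 295651 and 306001, where it changed by -0.78, -0.80 and -0.67. Their ratios in hydroxyurea were -0.09, -0.09 and -0.02, with counting intervals that all include 0, so they are not shown to have gone the other way. With a pseudocount of 50% of the median their untreated ratios were 0.40, 0.47 and 0.42, under the size rule, and the changes -0.45, -0.52 and -0.43. In the other direction, 73 of the 199 blocks at -0.5 or less in untreated cells had a value above 0 in hydroxyurea. The median over all blocks in hydroxyurea was 0.01, so most blocks lie above 0 there and these 73 of 199 are no excess. Of the 199 blocks, 177 were in the class with the most H3.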

How the results depend on the processing

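Settings for centring, H3 classes, odd and even windows, chromosome ends, ratio windows and domains were chosen only after the data had been seen. Against 212 called blocks in untreated cells, a pseudocount of 50% of the median gave 97, division by library medians 325 (13 higher, 312 lower), the mean of window log ratios 89, centring 115, subtraction of class medians 29, and a size rule of 1 gave 3. Against 111 in hydroxyurea, the 50% pseudocount gave 51, no H3 filter 193, an H3 filter at 50% gave 64 and a size rule of 1 gave 19. Against 459 for the change, the counts were 217 with the 50% pseudocount, 302 when centred, 162 with class medians subtracted and 27 at a size rule of 1. The wider part of the hydroxyurea peaks overlapped 71 of the 87 untreated peaks (81.6%), since fewer peaks were used. Of ratio windows, 803 in untreated cells became 244 at a ratio of 3 and 229 at 200 reads, and 2231 in hydroxyurea became 1183 and 1399. Domain length went from 2662.8 to 1348.5 kb at 0.25 over the median. The authors' difference was above 0 in 45.5% and 44.6% of windows once tracks were divided by their medians, for hydroxyurea and untreated cells. Stricter size rules, ratios and read minimums lower counts by construction, and for the other settings the cause was not tested. Of 404 alternatives for the 45 values of named blocks, 403 kept the direction and 326 stayed within 1 jackknife SE. The exception was the untreated ratio at chromosome 11 from 1, at -0.0061 from odd windows. These totals overstate stability. In 21 of the 404, blocks near chromosome ends were left out, which cannot change another block's value. A pseudocount cannot turn the sign of the ratio in 1 condition. The named blocks were the most extreme, and blocks at ends had wide errors. With the H3 filter at 50%, only 23 of the 45 values remained. The slope of the ratio change on the H3 change of neighbouring blocks, 0.19, became -0.030 with class medians subtracted. No paired analysis was possible because the groups share fewer than 2 replicate numbers, and with 1 library per group none could be left out. Alternatives that need gene positions (upstream regions, gene lists, origins, gene parts and peaks in genes) were not run. For the change of blocks, counting gave a median SE of 0.05, against 0.09 over windows, so depth is not the main limit there.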

Other observations

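All values and tests in this part were chosen after the data had been seen, except that 3 of the tests (slope over blocks, slope of the H3T45p change, and shuffled neighbours) were written down before their result was. Further criteria were added once the values were known, namely that the copy number slope include 1, that the mitochondrial ratio exceed the difference between the H3 libraries, and that all forms of the background test point the same way. The right end of chromosome 3, which held several of the highest untreated ratios, was examined as a stretch, and no other stretch was set against it. From 280501 to 316500, 22 of 23 blocks had a ratio above 0 in untreated cells, with a median of 0.35, against -0.03 in hydroxyurea. H3T45p was lower in hydroxyurea in 22 of the 23 blocks, with a median change of -0.35, and the median change of H3 was -0.12. Over the genome, the class of blocks with the least H3 had a median ratio of 0.14 in untreated cells and a median change of the ratio of -0.18. The 5 windows with the highest H3 in untreated cells were adjacent, on chromosome 12 from 459751 to 460500, at up to 74.1 times the library median. Chromosome 12 carries the repeated ribosomal DNA genes. There the log2 ratio of H3T45p over H3 was 0.62 (0.61 to 0.64) in untreated cells and 0.54 (0.53 to 0.56) in hydroxyurea. Of the 630 hydroxyurea peaks, 163 (25.9%, 22.5 to 29.5%) had their centre in a domain of raised H3, where 1000 shifts of the domains gave a mean of 136 and a central 95% range of 115 to 158. Of the 87 untreated peaks 16 did (mean of shifts 20.8).

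The called regions lay where H3 is low, as their high ratios over H3 favour. An even background of DNA in the H3T45p libraries would also favour such regions. In the hydroxyurea libraries the untreated peaks held 11.8 times (10.5 to 14.4) the H3T45p signal fitted from H3 plus an even background, so an even background is not enough there. In hydroxyurea, the windows of the hydroxyurea peaks had medians of 306 for H3T45p and 59.8 for H3. The nuclear lower quartile of that H3T45p library was 158, and its fitted even background 1.22. An even background is therefore not enough for the hydroxyurea signal at these peaks, though the call itself favours a high ratio there. For the untreated signal at hydroxyurea peak windows outside the untreated peaks, the forms of the test differed. In the untreated libraries these windows held 1.17 times (1.11 to 1.24) the H3T45p signal of other windows with the same H3. Against a line fitted to other windows the ratio was 1.04 (1.00 to 1.08), and without the peaks that touch an untreated peak these ratios were 1.14 (1.08 to 1.21) against matched windows and 1.01 (0.99 to 1.05) against the line, so an even background stays open for the untreated signal at these. An excess recovery of DNA at open sites was not tested, because no input or mock library was among the 4, and neither was a biological explanation.

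In untreated cells H3T45p relative to H3 fell with the H3 level. Longer DNA fragments that blur the untreated signal between neighbouring windows were argued against, since the slope on the H3 level of the other condition was -0.26 over blocks and -0.23 over windows, a quotient of 1.14 where blurring would lower it. More background DNA in the untreated than in the hydroxyurea H3T45p library stays open. The mitochondrial share relative to H3 was 0.88 times (0.81 to 0.96, counting error only) as high in untreated cells as in hydroxyurea, where more background would raise it, but the mitochondrial share itself differed 1.45-fold between the H3 libraries. A fitted even background of 60.8 in untreated cells and 1.22 in hydroxyurea describes the same fall with H3, so it is no separate support. The mitochondrial reads gave no sign of a difference of that size. In the H3T45p libraries they were 316 per 1000000 in untreated cells and 519 in hydroxyurea, the opposite order. Whether mitochondrial reads follow the background in nuclear windows was not tested. The treatment and any batch shared with it stay open, untested.

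The broad domains of raised H3 in hydroxyurea were not chance neighbours. The H3 change of a block correlated with the mean of its neighbours at 0.688, where the highest of 100 shuffles within chromosomes gave 0.149. DNA copy number is a candidate explanation, since hydroxyurea stalls replication after early origins have fired and both antibodies would then recover more DNA from replicated stretches. The slope of the H3T45p change on the H3 change of the neighbours was 1.17 (1.13 to 1.21), inside the range set for copy number beforehand but above 1. Any cause that raises the recovery of H3 in a stretch would also give a slope near 1, so copy number cannot be told apart from these without an input library. The change of the ratio of H3T45p over H3 had a slope of 0.19 ± 0.02 (jackknife SE over chromosomes), and of -0.03 ± 0.02 once the median of each class of H3 signal was subtracted. Domains were not set against named origins, and a batch shared with the treatment stays open.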
